A study of Homo sapiens with 6 samples.

How the data were processed

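Total RNA of 6 samples of a tamoxifen-resistant derivative of MCF-7, an established breast cancer cell line, was sequenced as Illumina libraries, per the labels' protocols. The libraries formed 3 groups of 2: cells with the empty pLKO lentiviral vector (control) and cells with either of 2 hairpins against DLL1, called DLL1-KD1 (hairpin sh64) and DLL1-KD2 (hairpin sh65). All cells grew in Iscove's medium with serum, penicillin and streptomycin and were detached with trypsin before lysis. The design text writes the sh64 line without its tamoxifen-resistance tag, while the sample titles carry the tag for all 6, and the titles were followed. Every column of the table was matched to a sample by its title.

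The authors deposited one table of raw read counts, 58294 genes by 6 libraries, with no normalization. The aligner, the counting program, the strand setting and the build are not given in the sources used here. All 58294 versioned Ensembl identifiers were found with the same version in GENCODE release 29 (GRCh38), from which symbols, coordinates and exon lengths were taken. Total counts ranged from 14904722 to 25242545 per library, and 32540 genes had no read in any library. Reads carried no molecular identifiers, so a floor of 3 counts, used where a group had no read, covers counting error only.

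The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust estimation) on the counts as deposited, with TMM factors, edgeR's expression filter by group, and one fit of all 6 libraries, so that the 3 groups shared one estimate of the spread. It kept 15130 genes. The biological coefficient of variation was 0.077 and the prior degrees of freedom were 15.8. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each knockdown was compared with control, the knockdowns with each other, and their mean with control. CPM values were computed from the TMM-scaled library totals, log2 CPM used a prior count of 2, and intervals of fold changes are 95% intervals. With 2 libraries per group, the spread rests on few samples, and nothing says whether repeats came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

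Gene lists, 33 in all, were fixed before the data were examined, and 853 of their genes were matched in the table. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. No list passed in any comparison with the estimated correlation, where the lowest adjusted p was 0.324 for DLL1-KD1, 0.366 for DLL1-KD2, 0.346 between the knockdowns and 0.492 for their mean. That setting also rests the test on the few residual degrees of freedom of 6 libraries in 3 groups, so hardly any list could pass. The luminal list of DLL1-KD1, with an estimated correlation of -0.004, still went from a camera adjusted p of 0.0397 to 0.324. Not passing there is thus no evidence that a list did not move, nor does it show the preset value to be right. Counts of list members adjusted over the list alone are given beside those over all genes.

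The genes named were chosen by a rule written before the data were examined. It took DLL1, a set of genes of interest, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change per knockdown, 10 up and 10 down for both knockdowns, and 5 up and 5 down between them. Such a gene had to be called, have a mean log2 CPM of at least 1, have a symbol that is no clone name, and have both libraries of one group above both of the other. From each list the rule took up to 4 members with the smallest p per comparison. The 44 genes of opposite direction were looked at after the data were seen, and genes named outside the rule are marked as chosen after their values were seen. Named genes were compared with all other annotated transcripts by shared 50-base words and by overlapping exons on either strand, since the counting could split, lose or mix such reads. Beside the genes marked as uncertain with their values, CRIP1, VIM, UHRF1, MCM2, CIITA, MTHFD2, TIGAR, ITGB6 and HIST1H2BK shared at least 20% of their words or exon bases with another gene and are uncertain for that reason. Smaller overlaps, such as 13.2% of the exon bases of NOS3 with ATG9B, were left as they are.

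The test was checked on simulated counts for DLL1-KD1 against control (14914 genes fitted). It recovered 61.8% of genes changed 1.5-fold, 69.7% of those changed 2-fold and 81.8% of those changed 4-fold, while 15 of 157 calls (9.6%) were false, above the nominal 5%. With no gene changed it called 4. These counts were drawn with non-robust dispersions, a choice made after a simulation with robust ones had given 23 false calls among 170 (13.5%), so the calls here may hold more false ones than the threshold states. Repeats were compared before use. Their counts differed by more than sampling noise, with chi-square per degree of freedom of 8.01, 12.4 and 7.22 for control, DLL1-KD1 and DLL1-KD2, so none was a repeat deposit.

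Alternatives planned before the data were examined were RLE and upper-quartile factors, library totals, no filter or a stricter one, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, the replicate number as a block, each library left out, and stricter thresholds. Non-robust estimation and edgeR's newer quasi-likelihood method were added after seeing the data. Figures were drawn with matplotlib.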

Results

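RNA was sequenced from tamoxifen-resistant MCF-7 cells, an estrogen receptor positive breast cancer line selected to grow in the presence of the antiestrogen, to compare empty-vector cells with cells carrying hairpins against DLL1, a membrane ligand of the Notch receptors. There were 2 libraries of empty-vector control cells, 2 labelled DLL1-KD1 and 2 labelled DLL1-KD2, each label standing for 1 hairpin. Total counts were 19728747 and 14904722 in control, 18626463 and 17469549 in DLL1-KD1, and 25242545 and 16070978 in DLL1-KD2. Mitochondrially encoded genes took 7.24% and 5.49% of the counts in control, 4.35% and 6.1% in DLL1-KD1, and 6.23% and 5.99% in DLL1-KD2. Each of the 6 libraries correlated best with the other library of its own label.

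DLL1 itself (ENSG00000198719.8, GRCh38 chromosome 6, 170282206 to 170306565, minus strand) was present at 126 and 105 counts in control, 92 and 118 in DLL1-KD1, and 106 and 70 in DLL1-KD2. Its level was 6.74 ± 0.376 CPM in control (SD, n = 2), 5.82 ± 1.24 in DLL1-KD1 and 4.29 ± 0.05 in DLL1-KD2. The libraries labelled DLL1-KD1 held 86.4% of the control level (95% interval 66.8 to 111.8%), a log2 fold change of -0.21 (SE 0.18, adjusted p = 0.555, edgeR), so no fall passed the test. This value was -0.03 without DLL1-KD1 replicate 1 and -0.44 (adjusted p = 0.291) without replicate 2. The libraries labelled DLL1-KD2 held 63.9% (49.0 to 83.1%), a log2 fold change of -0.65 (SE 0.18), which missed the threshold at an adjusted p of 0.0538. That value is adjusted over all tested genes. For DLL1 alone, the gene targeted, the unadjusted p was 0.00211 (edgeR). The adjusted p of this fall was 0.0477 with RLE factors and 0.0218 with no filter, but 0.102 with limma-voom and 0.31 with DESeq2. Between the knockdowns the log2 fold change was -0.44 (95% interval -0.82 to -0.05, unadjusted p = 0.028, adjusted p = 0.11, edgeR). No exon of another annotated gene overlaps a DLL1 exon, although the plus-strand gene FAM120B spans part of the locus. Because DLL1 did not fall measurably with 1 of the hairpins, directions below are those of the libraries labelled DLL1-KD1 and DLL1-KD2, not of a measured loss of DLL1.

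**Figure D1:**
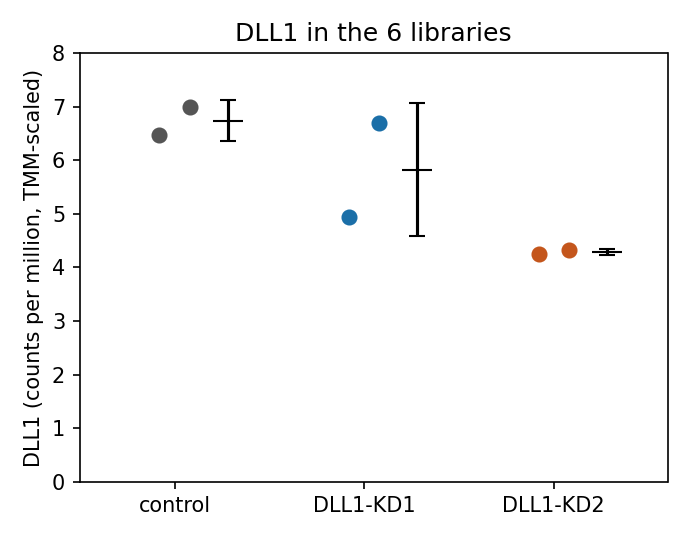
DLL1 in CPM of the TMM-scaled library. Each point is 1 library, and the bar beside each pair is the mean with its SD (n = 2). Control libraries lie at 6.47 and 7, DLL1-KD1 libraries at 4.94 and 6.69, and DLL1-KD2 libraries at 4.26 and 4.33.

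Genes of the Notch pathway otherwise moved little against control. NOTCH1, NOTCH2, NOTCH3 and NOTCH4 passed the test in neither knockdown, with log2 fold changes of 0.13, 0.09, 0.02 and 0.02 in DLL1-KD1 and -0.40, -0.23, -0.14 and 0.05 in DLL1-KD2. About 23.4% of the NOTCH2 sequence words recur in other genes, chiefly NOTCH2NLA, so its count is uncertain. Of the other ligands, JAG1 fell in DLL1-KD1 (log2 fold change -0.45, SE 0.12, adjusted p = 0.0246) and was at -0.21 in DLL1-KD2 (adjusted p = 0.371). Among 17 measured Notch target genes, 1 rose in DLL1-KD1, HEY2 (0.91, SE 0.24, adjusted p = 0.0203), and none was called in DLL1-KD2. Among them HES1, HEY1 and NRARP stood at -0.16, -0.20 and 0.01 in DLL1-KD1 and 0.08, 0.09 and -0.16 in DLL1-KD2, none of them called. Adjusted over the list alone, 1 target gene rose in DLL1-KD1 and none changed in DLL1-KD2, and 1 processing gene fell in each. The 9 measured ligands and receptors include DLL1. Adjusted over that list alone, 1 of them rose and 1 fell in DLL1-KD1, and 1, DLL1 itself, fell in DLL1-KD2. The 3 Notch lists (ligands and receptors, targets, processing and nuclear factors) did not pass camera in any comparison, with adjusted p of 0.901, 0.901 and 0.479 in DLL1-KD1 and 0.142, 0.591 and 0.466 in DLL1-KD2. In the processing list, the ubiquitin ligase ITCH fell in DLL1-KD1 (-0.35, adjusted p = 0.0265) and the sheddase ADAM10 fell in DLL1-KD2 (-0.35, adjusted p = 0.0436). Each of these 4 calls was lost in more than 1 of the fits that left out a library. JAG1 lost it without any 1 of the control and DLL1-KD1 libraries (-0.42 without DLL1-KD1 replicate 2). HEY2 lost it without control replicate 2 (0.64) or DLL1-KD1 replicate 2 (0.80). ITCH lost it without control replicate 1 (-0.28) or either DLL1-KD1 library (-0.38 and -0.33). ADAM10 lost it without either control library (-0.32 and -0.39), DLL1-KD1 replicate 2 (-0.35) or DLL1-KD2 replicate 1 (-0.24). ITCH lies within 32.3 to 36.6 Mb of chromosome 20, where 53 tested genes had a median of -0.25 in DLL1-KD1.

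In the libraries labelled DLL1-KD1, 1159 of 15130 genes differed from control, 601 higher and 558 lower, and 178 of them by 2-fold or more. BST2, an interferon-induced membrane protein that tethers virions, went from 1.56 ± 0.411 to 8.19 ± 1.79 CPM (5.16-fold higher, adjusted p = 5.75e-06). LGALS3BP, a secreted glycoprotein that binds galectin 3, went from 7.51 ± 0.313 to 28.3 ± 0.628 CPM (3.77-fold, adjusted p = 1.68e-08). The endothelial nitric oxide synthase NOS3 (4.33-fold), the netrin receptor UNC5C (4.12-fold), the calcitonin receptor CALCR (3.98-fold), NAV3 (3.86-fold), the fatty acyl-CoA reductase FAR2 (3.71-fold) and the prostaglandin E2 receptor PTGER3 (3.56-fold) were higher as well. TMTC1 had no read in either control library and 21 and 17 counts in DLL1-KD1, at least 12-fold higher than a floor of 3 counts over the control group. Lower genes were led by the adhesion molecule CNTN4 (3.83-fold lower, adjusted p = 1.97e-06), the RNA-binding protein RBMS3 (3.79-fold, from 9.56 ± 1.18 to 2.51 ± 0.214 CPM), PRSS42 (3.61-fold), the polyamine transporter SLC18B1 (3.61-fold) and the lipogenic regulator THRSP (3.54-fold). They were followed by UGT1A6 (3.47-fold), the mitochondrial glutamate carrier SLC25A18 (3.42-fold), the myosin light chain MYL3 (2.72-fold) and GRAMD2A (2.58-fold). CNTN4, RBMS3, PRSS42 and MYL3 lie on chromosome 3. UGT1A6 shares 59.9% of its sequence words with other genes of its cluster and is uncertain. SMIM11A (3.47-fold higher) and SMIM11B (4.07-fold lower) are near-identical copies whose summed count did not change (log2 fold change -0.03, adjusted p = 0.939), so neither change can be read on its own. Leaving out 1 library moved the count of called genes to 616 or 644 without either control library and to 490 without DLL1-KD1 replicate 2. Among these named genes only SLC25A18 lost its call without 1 library, with an adjusted p of 0.0847 without control replicate 2, 0.182 without DLL1-KD1 replicate 1 and 0.196 without replicate 2.

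The G2/M list was lower and the S phase and replication list higher in these libraries. Of 34 measured G2/M genes, 20 fell and none rose (24 fell adjusted over the list alone), with a median log2 fold change of -0.41 (camera adjusted p = 3.35e-13; adjusted p = 0.324 with an estimated correlation). Examples were the mitotic kinase AURKA (-0.59, SE 0.08), the ubiquitin-conjugating enzyme UBE2C (-0.62, SE 0.10), the spindle factor TPX2 (-0.54, SE 0.08) and DLGAP5 (-0.67, SE 0.11). Of 37 S phase and replication genes, 8 rose and none fell (11 rose and 1 fell adjusted over the list alone), with a median of 0.23 (adjusted p = 7.37e-06; adjusted p = 0.324 with an estimated correlation). They included the helicase subunits MCM2 (0.44, SE 0.08) and MCM5 (0.38, SE 0.09), the licensing factor CDT1 (0.48, SE 0.10) and UHRF1 (0.50, SE 0.10). Each of these 4 lost its call without 1 library, with adjusted p of 0.0614, 0.109 and 0.0682 for MCM2, MCM5 and CDT1 without control replicate 1 and 0.051 for UHRF1 without DLL1-KD1 replicate 2. MCM5 was also lost without control replicate 2 (0.0691) or DLL1-KD1 replicate 1 (0.0811), and CDT1 without DLL1-KD1 replicate 2 (0.0525). MKI67 was at -0.21 (SE 0.23, adjusted p = 0.69). MCM2 lies within 122.4 to 131.0 Mb of chromosome 3, where 67 tested genes had a median of 0.31 in DLL1-KD1.

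The 2 lipid synthesis lists were lower in DLL1-KD1, although most of their genes did not pass. In the cholesterol list 8 of 24 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.000426). Among them FDPS (-0.58), HMGCS1 (-0.43) and MSMO1 (-0.46) fell, while LSS rose (0.44). The call of MSMO1 was lost without DLL1-KD1 replicate 2 (-0.37). FDPS lies within 151.8 to 159.9 Mb of chromosome 1, where 131 tested genes had a median of -0.35 in DLL1-KD1. In the fatty acid list 5 of 21 fell (9 adjusted over the list alone; median -0.16, adjusted p = 0.000282), with THRSP, ACSS2 (-0.70) and ELOVL6 (-0.52) in front. Of 26 p53 target genes 7 rose and none fell (8 rose adjusted over the list alone; median 0.11, adjusted p = 0.01), led by TP53INP1 (1.11, SE 0.12) and PLK2 (0.50, SE 0.08). In the luminal epithelial list 5 of 27 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.0397), including the estrogen receptor ESR1 (0.45, SE 0.08, adjusted p = 0.00243) and TFF3 (0.59, SE 0.10). With an estimated correlation each of these 4 lists had an adjusted p of 0.324. Replication-dependent histone genes were higher (5 of 17 rose, 1 fell; 7 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.00317, and adjusted p = 0.467 with an estimated correlation). Unfolded protein and amino acid stress genes were lower as a list (1 of 31 rose and 1 fell, likewise adjusted over the list alone; median -0.07, adjusted p = 0.0468, and adjusted p = 0.597 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -0.39 (adjusted p = 0.00467, and adjusted p = 0.672 with an estimated correlation) with no member called, while the mitochondrial share of counts varied between control libraries as given above.

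Markers of other cell types were few. Of the fibroblast list 5 of 16 genes were measured and of the leukocyte list 3 of 20, and both were higher as lists in DLL1-KD1 (adjusted p = 0.0222 for each; adjusted p = 0.324 with an estimated correlation). Among them COL1A1 rose (0.54, SE 0.13, adjusted p = 0.017) and no other was called over all genes, while 2 of each list rose adjusted over the list alone. One of the 3 leukocyte genes is CD68, whose count is uncertain for the shared sequence given below. The call of COL1A1 was lost without control replicate 2 (0.169) or DLL1-KD1 replicate 2 (0.204). Endothelial markers did not pass (5 of 12 measured, 1 rose, 1 adjusted over the list alone; adjusted p = 0.175), although ENG rose (2.17, SE 0.33, adjusted p = 0.000475).

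In the libraries labelled DLL1-KD2, 578 genes differed from control, 261 higher and 317 lower, and 100 of them by 2-fold or more. TMTC1, at 102 and 81 counts, was at least 51.2-fold above the floor for the control group. GALNT5, an enzyme of mucin-type O-glycosylation, went from 0.505 ± 0.134 to 5.95 ± 1.55 CPM (11.8-fold, adjusted p = 1.49e-06). The ligand BMP5 (5.74-fold), BRINP2 (3.82-fold), the branched-chain amino acid transaminase BCAT1 (3.01-fold), NECAB1 (2.96-fold), the heparan sulfate sulfatase SULF1 (2.76-fold) and the imprinted gene PEG10 (2.66-fold) were also higher. Lower genes included the lysosomal glycoprotein CD68 (4.43-fold lower, adjusted p = 3.82e-06), CALML5 (3.7-fold), the adenosine receptor ADORA1 (3.13-fold), the BMP antagonist CHRD (3.13-fold), the immune checkpoint ligand VTCN1 (2.72-fold), SCUBE3 (2.64-fold), GRAMD2A (2.53-fold) and HGD (2.5-fold). CD68 and KBTBD11-OT1 (6.09-fold lower) share 78.2% and 98.1% of their sequence words with overlapping genes and are uncertain. SULT1A4 (2.74-fold higher) is nearly identical to SULT1A3, and their summed count was at 0.09 (adjusted p = 0.774); SMIM11A and SMIM11B summed to 0.28 (adjusted p = 0.273). The count of called genes was 259 and 276 without either control library and 223 without DLL1-KD2 replicate 1. Without control replicate 1, the calls of VTCN1 (adjusted p = 0.0531), SCUBE3 (0.0706), KBTBD11-OT1 (0.0699) and SULT1A4 (0.154) were lost, the last also without control replicate 2 (0.108).

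Many of the lower genes of DLL1-KD2 lay on chromosome 6, which carries DLL1. Of 790 genes tested there, 96 were lower and 10 higher, so that chromosome 6 held 96 of all 317 lower genes. Its median log2 fold change was -0.19, against values from -0.03 to 0.09 for the other chromosomes. The running median over 51 neighbouring genes stayed below -0.2 from 0.3 to 24.5 Mb, from 43.5 to 54.9 Mb and from 81.8 to 150.3 Mb, where 98, 52 and 214 genes had medians of -0.27, -0.21 and -0.26. DLL1 lay outside these runs, and 55 tested genes around it had a median of -0.13. In DLL1-KD1 the corresponding runs lay elsewhere. On chromosome 1 from 151.8 to 159.9 Mb, a stretch that holds FDPS and S100A9, 131 genes had a median of -0.35. On chromosome 13 from 72.7 to 114.3 Mb 89 genes had a median of 0.37. Of the 255 tested genes of chromosome 13, 63 were called higher and 3 lower. On chromosome 3, 52 genes from 44.9 to 48.9 Mb, a stretch that holds PRSS42 and MYL3, had a median of -0.23. There, 67 genes from 122.4 to 131.0 Mb, a stretch that holds MCM2, had one of 0.31. The windows and limits of these runs were chosen after seeing the data, as was their comparison with 100 shuffles of the genes within each chromosome. In these the longest runs held 4 genes on chromosome 1 and 3 on chromosome 3 in DLL1-KD1, 209 on chromosome 13 in DLL1-KD1 and 185 on chromosome 6 in DLL1-KD2. The runs on chromosomes 1 and 3 were thus longer than those of the shuffles, as was the run of 214 genes on chromosome 6. The runs on chromosome 13 and the other 2 on chromosome 6 were not, and these chromosomes had medians of 0.22 and -0.19.

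**Figure D2:**
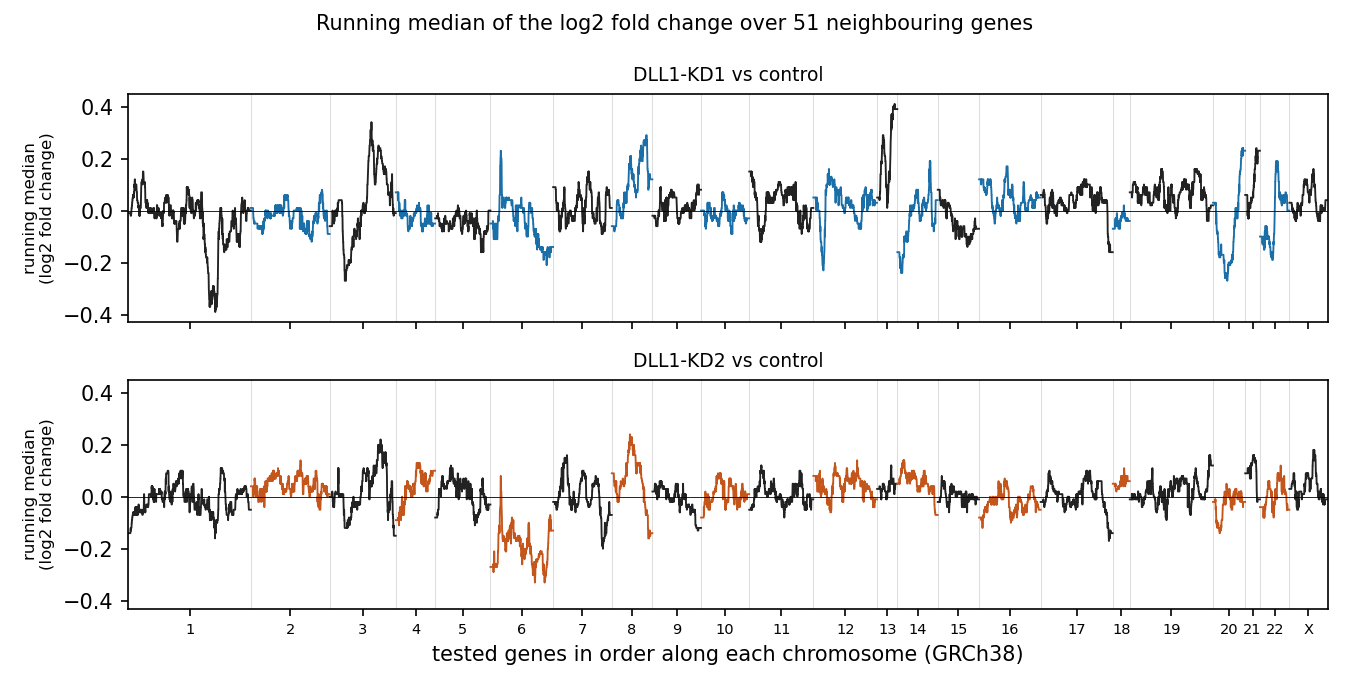
Running median of the log2 fold change against control over 51 neighbouring tested genes, in gene order along each chromosome, for DLL1-KD1 (upper panel) and DLL1-KD2 (lower panel). Chromosome 6 lies below 0 in DLL1-KD2 along most of its length (median of its genes -0.19), while DLL1-KD1 shows stretches on chromosomes 1 and 3 and on 13.

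In DLL1-KD2 the G2/M, S phase, cholesterol and stress response lists passed in the direction opposite to DLL1-KD1, while the p53 target and histone lists passed in the same direction. Of the 34 G2/M genes 4 rose and none fell (17 rose adjusted over the list alone; median 0.24, adjusted p = 1.46e-08), namely CCNB1 (0.50, SE 0.08), AURKA (0.47, SE 0.08), CENPA (0.70, SE 0.13) and UBE2C (0.45, SE 0.09). Of the 37 S phase genes 3 fell, MCM3 (-0.76, SE 0.08), MCM5 (-0.45, SE 0.09) and UHRF1 (-0.48, SE 0.10), and none rose (7 fell adjusted over the list alone; median -0.16, adjusted p = 5.97e-06). HMGCS1 (0.40) and STARD4 (0.39) rose in the cholesterol list (2 of 24, also adjusted over the list alone; median 0.13, adjusted p = 0.00812). ATF3 (0.63) and MTHFD2 (0.33) rose among stress response genes (2 of 31, and 6 adjusted over the list alone; median 0.17, adjusted p = 0.00117). The p53 targets were again higher, with TIGAR (0.46) and TNFRSF10B (0.35) called among 26 (5 adjusted over the list alone; median 0.15, adjusted p = 0.00117). Interferon response genes were higher (3 of 28 rose, 4 adjusted over the list alone; median 0.19, adjusted p = 0.00165), namely PARP9, HERC6 and HERC5. Antigen presentation genes were higher too (3 of 22 rose and 1 fell, 9 and 3 adjusted over the list alone; median 0.23, adjusted p = 0.0105). The members that rose belong to the class II pathway, CD74 (1.06, SE 0.17), HLA-DRA (1.14, SE 0.30) and HLA-DRB1 (1.29, SE 0.35), and TAPBP of the class I pathway fell (-0.45, SE 0.08). HLA-DRA lost its call without either control library (0.0826 and 0.241) or either DLL1-KD2 library (0.0963 and 0.193), and HLA-DRB1 without any of the libraries (up to 0.423 without DLL1-KD2 replicate 1). With an estimated correlation each of these 7 lists had an adjusted p of 0.366.

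Many of these calls in DLL1-KD2 were lost without 1 library. Without DLL1-KD2 replicate 1 the adjusted p became 0.078 for CENPA, 0.167 for UBE2C, 0.073 for UHRF1, 0.308 for HERC5 and 0.167 for TIGAR, and it was 0.0567 for MCM5 without control replicate 2. Without control replicate 1 it was 0.0726 for HMGCS1, 0.178 for STARD4, 0.206 for MTHFD2, 0.305 for TIGAR and 0.229 for PARP9. Without control replicate 2 it was 0.164 for ATF3, 0.206 for MTHFD2, 0.234 for TNFRSF10B, 0.2 for HERC6 and 0.362 for HERC5. STARD4, ATF3, MTHFD2, TNFRSF10B, PARP9 and HERC6 were lost without any 1 of the control and DLL1-KD2 libraries. HMGCS1, UBE2C and UHRF1 were lost without either control library or DLL1-KD2 replicate 1, MCM5 also without that replicate (0.0548), and TIGAR and HERC5 without DLL1-KD2 replicate 2 as well (0.0609 and 0.0787).

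In the extracellular matrix and integrin list 8 of 31 genes fell in DLL1-KD2 and none rose (8 fell and 1 rose adjusted over the list alone; median -0.18, adjusted p = 0.00117, and adjusted p = 0.52 with an estimated correlation), among them ITGB8 (-0.99, SE 0.17), COL18A1 (-0.56, SE 0.10), ITGB6 (-0.55, SE 0.10) and ITGA3 (-0.44, SE 0.09). Without DLL1-KD2 replicate 1 the calls of ITGB6 (0.076) and ITGA3 (0.087) were lost. In the heat shock and dissociation stress list 5 of 32 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.09, adjusted p = 0.0191, and adjusted p = 0.379 with an estimated correlation), led by HSPA1A (-0.62) and HSPA1B (-0.51), copies that share over 70% of their words and whose reads cannot be separated. Of these 5 lower genes 4 lie on chromosome 6, where the median of all genes was -0.19, as do MCM3, TAPBP, SCUBE3 and HIST1H2BK. Oxidative phosphorylation genes were higher (5 of 37 rose and 1 fell, 7 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.0015), as were cytoplasmic ribosomal protein genes (none of 44 called, none adjusted over the list alone; median 0.14, adjusted p = 0.000434), both with an adjusted p of 0.617 with an estimated correlation. Histone genes had a median of 0.28 (adjusted p = 0.00165, and adjusted p = 0.366 with an estimated correlation) although the 1 called member, HIST1H2BK, fell (5 rose and 1 fell adjusted over the list alone) and lost its call without control replicate 2 (0.169) or DLL1-KD2 replicate 2 (0.166). TGF-beta and BMP target genes were lower (1 of 24 fell, 2 adjusted over the list alone; median -0.07, adjusted p = 0.0386, and adjusted p = 0.366 with an estimated correlation), the called one being the pseudoreceptor BAMBI (-0.92, SE 0.09).

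Estrogen response genes moved in both directions. In DLL1-KD1 7 of 40 rose and 6 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.75), with STC2 at 1.34 (SE 0.08) and EGR3 and CISH at -0.63 each (SE 0.09). In DLL1-KD2 8 rose and 4 fell (11 and 5 adjusted over the list alone; adjusted p = 0.532), with the EGFR ligand AREG at 0.92 (SE 0.08), PDZK1 at 0.76 (SE 0.10) and the chemokine CXCL12 at 1.14 (SE 0.16). PDZK1 shares 54.1% of its words with a pseudogene. TFF1 fell in DLL1-KD2 (-0.41, SE 0.09, adjusted p = 0.00957) and was at 0.16 in DLL1-KD1 (adjusted p = 0.302). PGR, GREB1, GATA3 and FOXA1 passed in neither. ERBB2 fell in DLL1-KD2 (-0.36, SE 0.08, adjusted p = 0.0132), CD44 rose in DLL1-KD1 (0.54, SE 0.08, adjusted p = 0.000538), and EGFR, VIM, CDH1 and CSF1 were not called in either. TFF1 lost its call without either control library (0.0547 and 0.0693) or DLL1-KD2 replicate 2 (0.0958), and ERBB2 without either control library (0.0627 and 0.104) or DLL1-KD2 replicate 1 (0.122). VIM was at -0.59 and -0.60 with adjusted p of 0.0649 and 0.0831. IL34 and CCL2 had 2 and 0 counts over the 6 libraries and were not testable at this depth.

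The libraries labelled DLL1-KD2 differed from those labelled DLL1-KD1 at 2657 genes, 1284 higher and 1373 lower, more than either differed from control. MGP, a matrix protein that inhibits calcification, stood at 104 ± 0.768 CPM in control, 64 ± 1.15 in DLL1-KD1 and 276 ± 19.8 in DLL1-KD2, a 4.32-fold difference between the knockdowns (adjusted p = 1.49e-11). GALNT5 (14-fold), BMP5 (5.64-fold), TMTC1 (4.3-fold) and the chaperone CLGN (4.15-fold) were likewise higher in DLL1-KD2, and BST2 (6.02-fold), CD68 (6.03-fold), NAV3 (5.42-fold) and KBTBD11-OT1 (17.6-fold) lower. Of the G2/M genes 27 of 34 were higher and none lower in DLL1-KD2 (32 adjusted over the list alone; median 0.63, adjusted p = 6.23e-18), and of the S phase genes 21 of 37 were lower and none higher (25 adjusted over the list alone; median -0.38, adjusted p = 1.57e-10). Cholesterol synthesis genes were higher at 12 of 24 and lower at 1 (13 and 1 adjusted over the list alone; median 0.29, adjusted p = 1.68e-05). For these 3 lists the adjusted p was 0.346 with an estimated correlation. Stress response genes were higher at 14 of 31 and lower at 1 (16 and 1 adjusted over the list alone; median 0.26, adjusted p = 6.41e-05, and adjusted p = 0.36 with an estimated correlation), and luminal genes lower at 9 of 27 and higher at 2 (13 and 2 adjusted over the list alone; median -0.25, adjusted p = 0.00497, and adjusted p = 0.346 with an estimated correlation). Fatty acid synthesis genes were higher at 9 of 21 and lower at 1 (9 and 3 adjusted over the list alone; median 0.11, adjusted p = 0.00974, and adjusted p = 0.36 with an estimated correlation). Extracellular matrix and integrin genes were lower at 8 of 31 and higher at 2 (10 and 2 adjusted over the list alone; median -0.26, adjusted p = 0.00497, and adjusted p = 0.68 with an estimated correlation). Fibroblast markers were lower at 3 of 5 (4 adjusted over the list alone; median -0.49, adjusted p = 0.00769, and adjusted p = 0.346 with an estimated correlation), and leukocyte markers at 2 of 3 (2 adjusted over the list alone; median -1.55, adjusted p = 0.0391, and adjusted p = 0.36 with an estimated correlation), 1 of them the uncertain CD68. Oxidative phosphorylation genes were higher at 11 of 37 and lower at 1 (14 and 2 adjusted over the list alone; median 0.17, adjusted p = 0.00154, and adjusted p = 0.824 with an estimated correlation). Mitochondrially encoded genes were higher at 1 of 13 (1 adjusted over the list alone; median 0.34, adjusted p = 0.0391, and adjusted p = 0.824 with an estimated correlation), and ribosomal protein genes at 1 of 44 (none adjusted over the list alone; median 0.14, adjusted p = 0.0072, and adjusted p = 0.859 with an estimated correlation). The antigen presentation list is given further below. Basal, mesenchymal, stem cell, apoptosis, NF-kB, cytokine, growth factor, xenobiotic, hypoxia, Wnt and endothelial lists passed camera at the preset correlation in none of the comparisons. Some passed with fry, another list test of limma. These included the xenobiotic list in DLL1-KD1 (fry adjusted p = 0.00712), between the knockdowns (0.00407) and for their mean (0.0358). The basal list passed fry in DLL1-KD2 (0.0483) and between the knockdowns (0.0174), and the cytokine list between them (0.0237). The Notch lists did not pass (adjusted p from 0.441 to 0.886), although NOTCH1 (-0.53, SE 0.13, adjusted p = 0.0165) and JAG2 (-0.53, SE 0.12, adjusted p = 0.00595) were lower in DLL1-KD2. Both lost the call without DLL1-KD1 replicate 2 (0.158 and 0.123), and NOTCH1 also without DLL1-KD2 replicate 1 (0.123). The count of 2657 fell to 1090 without DLL1-KD1 replicate 2 and to 1295 without DLL1-KD2 replicate 1.

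**Figure D3:**
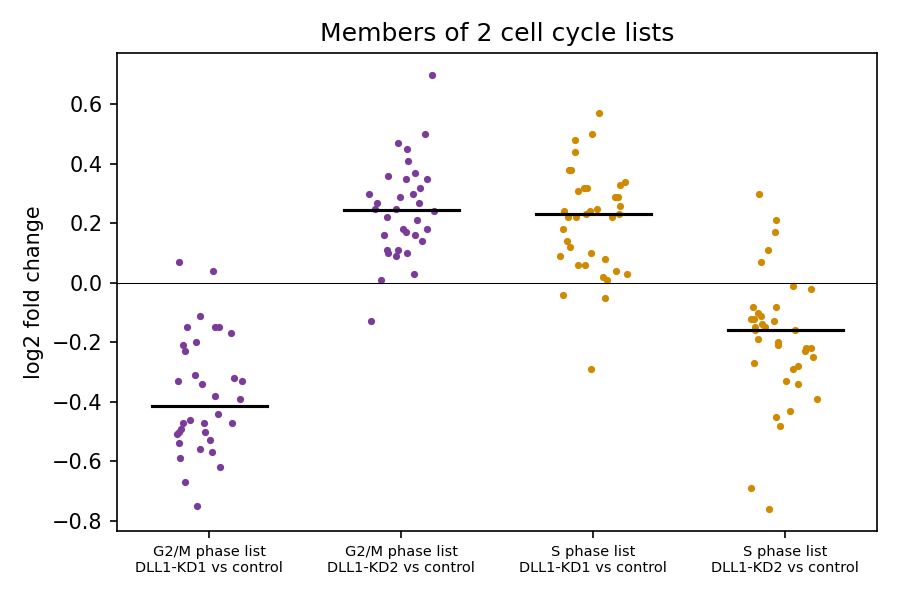
Log2 fold changes against control of the measured members of the G2/M list (34 genes) and the S phase and replication list (37 genes) in each knockdown. Each point is 1 gene, spread sideways at random, and each bar is the list median. Medians are -0.41 and 0.24 for G2/M and 0.23 and -0.16 for S phase.

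Both knockdowns changed 144 genes against control, 54 up in both, 46 down in both and 44 in opposite directions. Higher in both were SULF1 (3.16-fold and 2.76-fold, from 52.4 ± 2.8 CPM to 166 ± 3.02 and 145 ± 16.6), PTGER3 (3.56-fold and 2.52-fold), BCAT1 (2.44-fold and 3.01-fold), the semaphorin SEMA6A (1.88-fold and 2.65-fold) and TMTC1. Lower in both were GRAMD2A (2.58-fold and 2.53-fold), the glutamyltransferase family member GGT6 (1.74-fold and 2.19-fold) and the phospholipid flippase ATP8A2 (2.22-fold and 1.66-fold). These genes kept both calls in every fit that left out 1 library. CRIP1, SGK1, FAR2, S100A9, RAB7B, LOXL2, ADORA1, CHRD and ITGB8 were also called in both, and each lost a call without at least 1 library. In DLL1-KD2 the highest adjusted p was 0.289 for FAR2 and 0.284 for CRIP1 without DLL1-KD2 replicate 1, and 0.126 for RAB7B and 0.0667 for S100A9 without control replicate 2. In DLL1-KD1 it was 0.37 for CHRD without control replicate 2, 0.139 for LOXL2 and 0.0888 for ITGB8 without control replicate 1, and 0.0946 for ADORA1 and 0.0846 for SGK1 without DLL1-KD1 replicate 2. Independent lists of these lengths would share 22.1 genes in the same direction and 22.2 in opposite ones. Unchanged groups simulated against the same controls shared 0.5 and 0.0 on average over 20 simulations. Unchanged groups give almost no calls, so this overlap had to be small. It cannot show how many shared calls the shared controls bring to 2 changed lists. Splitting the controls would have left each knockdown 1 control library and was not done, so part of the excess over independent lists may come from their being shared. The count of 100 became 50 and 61 without either control library and 61 without DLL1-KD2 replicate 1.

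Across genes, the 2 sets of fold changes correlated at 0.39, against 0.51 for simulated unchanged groups, with a covariance of 0.0883 against 0.0326. Among 10207 genes of mean log2 CPM 3 or more, a limit set after seeing the data, the correlation was 0.10 against 0.50 and the covariance 0.0045 against 0.0081, a difference of -0.0036. Genes are not independent replicates, so no p is given. The mean of both knockdowns differed from control at 408 genes, 204 higher and 204 lower, or 156 and 157 without either control library. In that comparison p53 targets were higher (5 of 26 rose, 9 adjusted over the list alone; median 0.11, adjusted p = 0.000574, and adjusted p = 0.492 with an estimated correlation). Histone genes were also higher (3 of 17 rose, 4 adjusted over the list alone; median 0.32, adjusted p = 0.000635, and adjusted p = 0.644 with an estimated correlation), while fatty acid synthesis genes were lower (3 of 21 fell, 5 adjusted over the list alone; median -0.10, adjusted p = 0.00595, and adjusted p = 0.492 with an estimated correlation). Interferon response genes were higher (2 of 28 rose, 2 adjusted over the list alone; median 0.12, adjusted p = 0.00942, and adjusted p = 0.492 with an estimated correlation), and heat shock genes lower (3 of 32 fell and 2 rose, 4 and 2 adjusted over the list alone; median -0.09, adjusted p = 0.00983, and adjusted p = 0.644 with an estimated correlation). TGF-beta target genes were lower (2 of 24 fell and 1 rose, likewise adjusted over the list alone; median -0.11, adjusted p = 0.0315, and adjusted p = 0.492 with an estimated correlation). Mitochondrially encoded genes were lower (none of 13 called, none adjusted over the list alone; median -0.26, adjusted p = 0.0315, and adjusted p = 0.762 with an estimated correlation) and ribosomal protein genes higher (none of 44 called, none adjusted over the list alone; median 0.08, adjusted p = 0.0315, and adjusted p = 0.787 with an estimated correlation).

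**Figure D4:**
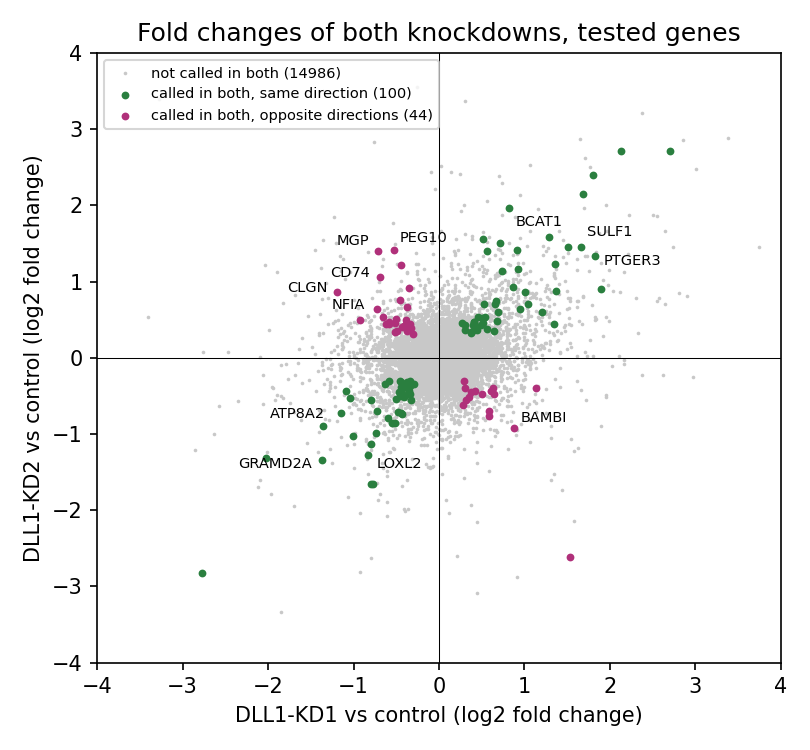
Log2 fold change against control in DLL1-KD1 (horizontal) and DLL1-KD2 (vertical), 1 point per tested gene. Green points (100) were called in both in the same direction, magenta points (44) in opposite directions, grey points were not called in both, and 39 genes beyond 4 on either axis are not drawn.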

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

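The tests of DLL1 and of the cell cycle lists below were chosen only after those results were seen; the tests of the count between the knockdowns were written before their outcome, but what leaves graded loss and a single library open was set after it. All differences here are those of DLL1-KD2 against DLL1-KD1, tested directly with edgeR.

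More genes differed between the knockdowns (2657) than between either and control. A graded loss of DLL1 is not decided by DLL1-KD1 lying between control and DLL1-KD2 in 6.81% of these genes. Genes picked for a difference between the knockdowns tend to leave control in between. The order of DLL1 was not called (adjusted p = 0.11, unadjusted p = 0.028, edgeR). Of 144 genes called in both against control, 44 went in opposite directions. If DLL1 was at or below control in both, these 44, looked at after the data were seen, argue against a graded loss that moves each gene 1 way. The interval for DLL1-KD1 reached 111.8% of control, so a graded loss stays open. GC content and gene length are argued against by offsets for both, which left 3157 genes called, 2216 of them also called without the offsets in the same direction, while a single deviating library stays open, since the order of the counts held in 6 of the 6 fits without 1 library but by only 1295 against 1260 for DLL1-KD1 without DLL1-KD2 replicate 1. Stretches of neighbouring genes that moved together existed (rank correlation of neighbouring genes 0.176, at most 0.0252 in 100 shuffles). Yet 1770 genes stayed called after the running median over 51 neighbouring genes was subtracted. A shift shared by such a neighbourhood may thus account for part but not for most of the count. Shorter stretches, genes that differ more than their neighbours, and effects of a stretch on genes elsewhere are not removed by this step and stay open. The smoothing at chromosome ends was changed after the count was first seen, then 1752. Effects of each hairpin on other transcripts, and differences between separately infected cultures, stay open and untested, as does a biological difference through DLL1.

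DLL1 was close to control in the libraries labelled DLL1-KD1 and lower in DLL1-KD2 without passing the test, at an adjusted p of 0.0538 against control and 0.11 against DLL1-KD1. Unadjusted, for DLL1 alone as the gene targeted, p was 0.00211 and 0.028 (edgeR). A swap between a control and a DLL1-KD1 library is argued against by 6 of 6 libraries correlating best with the other of their own label. An exchange of whole labels, with both libraries of each, would leave these correlations as they are and stays open. Reads too few to see a fall of 1 log2 unit in DLL1-KD1 are argued against by the lower 95% limit of -0.58 (-0.87 without DLL1-KD1 replicate 2, where DLL1 was at -0.44, against -0.03 without replicate 1), but a smaller fall, to 66.8% of control, stays within the interval. A lower level shared by the 55 tested genes around DLL1, from 152983331 to 170736545 on chromosome 6, is argued against for the value in DLL1-KD2. The median of these neighbours was -0.13, above the upper limit of -0.27 for DLL1. It was still above that limit without control replicate 2 (-0.10 against -0.13) or DLL1-KD2 replicate 1 (-0.09 against -0.15). DLL1 lies near the end of this span, so a lower level of a shorter stretch at the chromosome end is not excluded. A loss of DLL1 protein without loss of RNA, and recovery of expression during culture, stay open and untested.

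Genes of the G2/M and S phase lists moved in opposite directions in each knockdown, with adjusted p of the difference of 6.23e-18 and 1.57e-10 (adjusted p = 0.346 with an estimated correlation for both). One library of a pair is argued against by the difference of the list means, which was 0.59 and 0.52 in control, -0.05 and -0.01 in DLL1-KD1 and 0.97 and 0.99 in DLL1-KD2, with 6 of 6 libraries outside the ranges of the other groups. A different culture state at harvest and a cell cycle effect of the hairpins cannot be told apart, because 0 of the 6 samples have a passage, density or date in their labels. Another rate of proliferation was not tested.

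The cholesterol synthesis and stress response lists also moved apart, with adjusted p of the difference of 1.68e-05 and 6.41e-05 (adjusted p = 0.346 and adjusted p = 0.36 with an estimated correlation). Of 127 named genes 94 differed between the knockdowns, a share raised by a rule that picked some for this difference, against 2657 of 15130 tested genes (17.6%). In all, 44 genes were called in opposite directions in both with the difference called. Among the latter, log2 fold changes of DLL1-KD2 against DLL1-KD1 were -4.14 for KBTBD11-OT1, 2.11 for MGP, 2.05 for CLGN, 1.94 for PEG10, -1.81 for BAMBI, 1.75 for CD74, 1.36 for NFIA, 1.27 for AREG, 1.23 for PDZK1, 1.07 for UBE2C and 1.06 for AURKA. They were -0.97 for UHRF1, -0.90 for HSPA1A, 0.89 for CCNB1, -0.88 for COL18A1, -0.87 for HSPA1B, 0.84 for HMGCS1, -0.83 for MCM5 and 0.73 for STARD4. Of these, MGP, CLGN, BAMBI, NFIA and AURKA kept both calls against control in every fit without 1 library, and each of the others lost at least 1, with an adjusted p of up to 0.52 for COL18A1 in DLL1-KD1 without control replicate 1. BAMBI, CD74, MGP, CLGN, PEG10 and KBTBD11-OT1 come from the rule for named genes, as do the list members, and NFIA was chosen after its values were seen.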

How the results depend on the processing

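No DLL1 value changed sign under any alternative, nor did any named gene that was called in the main fit or in that alternative. Sign changes of named genes called in neither were not recorded. The balance of higher and lower calls did turn. Upper-quartile factors gave 297 higher and 274 lower in DLL1-KD2 (261 and 317 before) and 1444 and 1266 between the knockdowns (1284 and 1373 before), and the stricter filter 574 and 635 in DLL1-KD1 (601 and 558 before) and 44 and 59 in both (54 and 46 before). It also turned in DLL1-KD1 with DESeq2 (336 and 346) and without control replicate 1 (by 2 genes) or DLL1-KD2 replicate 1 (600 and 660), between the knockdowns without DLL1-KD2 replicate 1 (658 and 637), in both with the compared groups alone (42 and 52), and in DLL1-KD2 with a log2 fold change of at least 1 (65 and 35). Non-robust estimation and the newer quasi-likelihood method were chosen after seeing the data. Counts are given for DLL1-KD1, DLL1-KD2, between the knockdowns, the mean of both and the same direction in both, in that order, where the main counts were 1159, 578, 2657, 408 and 100. RLE and upper-quartile factors, library totals, the stricter filter, fits of the compared groups alone and the newer method moved no count by over 1.5 times. The mean of both uses every group, so a fit of the compared groups alone gave no other value for it. DESeq2 gave 682, 349, 1611, 258 and 56. limma-voom gave 359, 219 and 62 for DLL1-KD2, the mean and both, and non-robust estimation 354, 219 and 64. No filter gave 911, 670 and 170 for the same 3 counts. At an adjusted p under 0.01 the counts were 500, 202, 1219, 152 and 39, and with a log2 fold change of at least 1 also required 178, 100, 355, 65 and 21, as fewer genes pass a stricter limit. Leaving out 1 library gave 490 to 1260, 223 to 637, 1090 to 2716, 156 to 364 and 50 to 86. Its lone partner was then assumed to vary like the other groups, so fewer samples carry the test. For DLL1 the log2 fold change ran from -0.44 to -0.03 in DLL1-KD1, never called, and from -0.72 to -0.59 in DLL1-KD2 in these fits.

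The fall of DLL1 in DLL1-KD2, just short of the threshold at -0.65, passed it with RLE factors (-0.65), no filter (-0.64), the stricter filter (-0.66) and the compared groups alone (-0.65), and without either DLL1-KD1 library. Its adjusted p ran from 0.0218 with no filter to 0.31 with DESeq2. The cause was not tested.

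The replicate numbers were not taken to pair the samples, since deviations of same-numbered libraries correlated at -0.00, -0.05 and 0.06. These low values do not exclude a batch shared by same-numbered libraries. With the number as a block the counts were 1457, 853, 3174, 586 and 150, and DLL1 in DLL1-KD2 was at -0.64 and called.

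Of 246 calls of named genes, 166 held in every alternative, and of 4169 single comparisons 3868 kept the call and 301 lost it. Without at least 1 of the libraries 79 of the 246 were lost. In the alternatives for the gene lists, 12 results not called in the main test were called. Of 45 list calls, 27 held with fry, 40 with the block and 45 with RLE factors, and none with an estimated correlation. The last setting could let hardly any list pass, given the few residual degrees of freedom. At 14904722 to 25242545 counts and 2 libraries per group, 61.8% of simulated 1.5-fold changes were found.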

Other observations

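The tests and limits in this part were chosen after the data were seen, except the gene lists.

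The antigen presentation genes with the smallest p in DLL1-KD2 against DLL1-KD1 were CD74 at 1.75 (SE 0.18), HLA-DRA at 2.29 (SE 0.34), CIITA at 1.46 (SE 0.23) and HLA-DPA1 at 2.14 (SE 0.34). The antigen presentation list as a whole was higher there (7 of 22 rose and 2 fell, likewise adjusted over the list alone; median 0.16, adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation). In the interferon list BST2 (-2.59) went against UBE2L6 (0.95), HERC5 (1.26) and HERC6 (0.70), and the list did not pass (5 of 28 rose and 3 fell, 7 and 4 adjusted over the list alone; adjusted p = 0.544). The drug transporter ABCC2 was lower in DLL1-KD2 (-1.65, SE 0.16) and ABCG2 higher (1.07, SE 0.16), in a xenobiotic and retinoid list that did not pass (2 of 23 rose and 5 fell, 2 and 6 adjusted over the list alone; adjusted p = 0.189). Among stem cell markers CD44 (-0.73) and SOX2 (-0.69) were lower in DLL1-KD2 (1 of 12 rose and 4 fell, likewise adjusted over the list alone; adjusted p = 0.295).

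Stretches of neighbouring genes moved together. Of runs of at least 40 genes with a running median beyond 0.2, DLL1-KD1 had 9 against control with 588 genes and DLL1-KD2 had 3 with 364. The longest run in 100 shuffles of the genes over the genome held 7 and 0 genes. This comparison replaced shuffles within chromosomes, which had been run first and kept any shift of a whole chromosome. Those gave runs of up to 209 genes in DLL1-KD1, longer than the longest observed (131), and up to 185 in DLL1-KD2, shorter than the longest observed (214). Taken chromosome by chromosome and for runs of at least 40 genes, the longest run was above that of the shuffles on chromosomes 1 (131 against 4), 3 (67 against 3), 8 (58 against 31) and 20 (53 against 16) in DLL1-KD1, but not on 13 (89 against 209), and on chromosome 6 (214 against 185) in DLL1-KD2. On chromosome 6 from 81.8 to 150.3 Mb the replicates of DLL1-KD2 had medians of -0.26 and -0.23 against the control mean, and the control libraries 0.02 and -0.02. On chromosome 13 from 72.7 to 114.3 Mb the replicates of DLL1-KD1 had medians of 0.39 and 0.34, and on chromosome 1 from 151.8 to 159.9 Mb -0.33 and -0.36. The libraries agreed less on chromosome 20 from 62.4 to 64.3 Mb, with 0.16 and 0.29 in DLL1-KD1 and -0.09 and 0.09 in control. After offsets for GC content and gene length the medians of the first 3 stretches were -0.29, 0.36 and -0.39, while that on chromosome 20 went from 0.24 to 0.15, below the limit of a run. Between the knockdowns 3 runs also fell below it, on chromosomes 8 (-0.24 to -0.13), 9 (-0.23 to -0.06) and 20 (-0.29 to -0.16). No DNA was analysed here, and what the stretches reflect was not tested.

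ITM2A and SEMA4G, chosen after their values were seen, had no read in control and were at least 19.3-fold and 13.2-fold above the floor of 3 counts over the group in DLL1-KD2.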
